A study of Mus musculus with 3 samples.

How the data were processed

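The series holds total RNA profiles of 3 single-cell clones of FAB-SC, unstimulated, which are the 3 replicates of 1 group, each a separate clone with 1 array. Per the labels, RNA was extracted with Trizol, amplified and labelled with Cy3 by an Agilent kit, and hybridised to a 1-colour Agilent mouse array. Per the file headers, the arrays were read out with Feature Extraction 9.1.3.1. The deposited scanner files give, per the file headers, a processed intensity from which the scanner software had subtracted a fitted spatial background and which it had corrected for trends across the array. Where the intensity was not above its error, the software had put a small surrogate in its place. Per the file headers, nothing was normalized between arrays. The deposited flags are 0 or 1 for each spot and were set by the scanner software. The arrays were scanned on 1 day on 3 slides, so that clone and slide cannot be told apart, and no other batch could be compared. A genome build does not enter these values. Columns with the mean, the local background and the background-subtracted intensity of each spot served for checks and for 1 alternative.

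A deposited table of values for 41529 unnamed entries per clone was also at hand. Its column median is 1 in each column, which is what division of each array by its median would give, and the highest background-subtracted intensities are a constant multiple of its highest values, 19.3 in clone 1, 19.4 in clone 2 and 18.5 in clone 3. How the authors made this table is not stated. Its entries match neither the feature numbers nor the probe numbers of the scanner files. The rank correlation with the intensities was 0.00586, 0.00468 and 0.00370 by feature number and 0.00996, 0.0177 and 0.0165 by probe number, so no gene could be named from it, and it was used only for the overall spread between clones. A column that was divided by its own median cannot show a difference in total signal between arrays.

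Spots that the software marked as outliers were left out, 23, 9 and 6 on the arrays of clones 1, 2 and 3. Spots of the same probe were averaged as log2 intensity, and each array's 75th percentile over probes that were not controls was subtracted. The median intensity of these probes was 17.2, 17.6 and 16.3. Signal over background sets what the arrays can show, and the lowest intensity among probes well above background was 6.72, 6.79 and 5.94. The positive-and-significant flag was met by 71.8%, 73.5% and 73.3% of probes. The fit of the spike-in controls had an r2 of 0.996, 0.997 and 0.998. As a check for copied arrays, the share of spots with the same intensity in a pair of clones was between 0.649% and 0.769%.

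Probes were named by transcript identifier (22951 probes), else by gene symbol (6659), else by a synonym that points to 1 gene (3096), with a reference gene table that also gave each gene's chromosome and the order of genes on it. A further 2024 probes kept the name in the file, and 6444 had none. This gave 21301 genes, 19493 of them with a chromosome and 8832 with more than 1 probe. A gene was called detected on an array if any of its probes was well above background there. Its level came from the probe with the highest mean level. A gene counted as differing between clones if its highest and lowest clone differed by at least 1 on the log2 scale and its probe was well above background on all 3 arrays. For genes detected in some clones only, the fold is a lower bound. It sets the mean of the clones with signal against, for each other array, the higher of the lowest level among probes well above background and the probe's own level.

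Gene lists for 29 cell types, states, pathways and controls, with 361 members on the array, were fixed before the data were examined, as were the comparisons, the alternatives and the rule for naming genes. Whether members of a list were detected on all 3 arrays more or less often than other genes was tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 29 lists. The shift of a list in a clone is the median over detected members of its level minus the mean of the other 2 clones. The shift and the median SD over clones were ranked among 10000 random lists of the same size, matched on mean level in 20 bins. A value outside the central 95% of the random lists is called outside their range, and lists with fewer than 5 detected members were not ranked. Chromosomes were treated in the same way. With 1 array per clone no test between clones was made. No paired analysis was possible, because the samples form 1 group.

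The text names the first 4 members of each list that the array holds. It also names the member of each list with the largest range, if at least 1 on the log2 scale in a probe above background on all 3 arrays. It further names the 20 genes with the largest ranges, the 10 genes with the largest lower bounds among genes detected in some clones only, and the Y-linked genes with Xist, Meg3 and Cdh1. Some were left out for length, 1 gene is not reported here, and genes outside the rule are marked as named after their values were seen. Lists of further epithelial, posterior streak, axial mesendoderm and fibroblast genes were written after the first results had been seen, without looking at the values of their genes.

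The alternatives were another background correction (the normexp model of limma with an offset of 50), quantile normalization, the array median or the detected probes as the scale, the mean of a gene's detected probes, no background filter, a looser detection flag, a 4-fold rule, the deposited table, and leaving out each clone. Leaving out the genes of chromosomes 8 and 12, or of chromosomes 1, 2, 8, 11, 12 and 13, was added after the data were seen. The calculations were tested on simulated arrays of 13140 genes, with noise of the size seen between spots of 1 array, an SD of 0.115. Of 50 genes changed per size, 0 were called at 1.5-fold and 50 at 2.5-fold, and 0 of 12244 unchanged genes were called. A chromosome shifted by 0.3 was read as 0.30, and a list shifted by −0.4 as −0.37. Of 600 values of unshifted lists, 21 (3.5%) lay outside the range of random lists, and 7 of 200 random lists (3.5%) passed the detection test before adjustment. This noise is that within an array and does not cover differences between cultures. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.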

Results

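FAB-SC are mouse stem cells derived from blastocysts, and the series is titled for the growth factor environment and the pluripotent states it defines. Gene expression was profiled in unstimulated cells of 3 separate single-cell clones, each a culture grown from 1 cell. Total RNA was extracted with Trizol, labelled with Cy3 and hybridised to 1-colour Agilent arrays, 1 array per clone. The labels number the clones 1 to 3 as replicates of 1 group, and the stated purpose of the design was to characterise the cell type. No other cell type or treatment was compared, so genes were set against the array's background and the clones were set against each other. Each clone had 1 array on a slide of its own, so clone and slide cannot be told apart, and no difference between clones has a p-value. A gene's level is the log2 of its probe's processed intensity minus the log2 of the array's 75th percentile. Levels are given as mean ± SD over the 3 clones, and each gene is compared with itself between clones, never with another gene.

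Each array held 43379 spots that were not controls, for 41174 different probes. The scanner software marked 23421 probes (56.9%) as well above background in clone 1, 23853 (57.9%) in clone 2 and 23916 (58.1%) in clone 3. The 75th percentile of the processed intensity was 225, 216 and 208 in clones 1, 2 and 3. The median intensity of the 153 negative-control spots was 1.78, 1.69 and 1.48. No spot was saturated, with 0 on each array. Spots of the same probe on 1 array had a median SD of 0.117, 0.109 and 0.120 on the log2 scale. The number of arrays limits the precision of every value. Of 21301 named genes, 13151 (61.7%) were detected on all 3 arrays, 531 (2.49%) on 2 arrays, 751 (3.53%) on 1 array and 6868 (32.2%) on none.

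The first comparison asked which kinds of genes these cells express. Genes of the core pluripotency network, which hold early embryonic cells undifferentiated, were detected in all 3 clones in 15 of 16 cases. Pou5f1, which encodes the transcription factor Oct4, had a level of 5.58 ± 0.09 (SD, n = 3) and differed by at most 1.13-fold between clones. Nanog had a level of 3.63 ± 0.18 and Sall4 one of 4.05 ± 0.28, both encoding transcription factors of the same network. Sox2, the partner of Oct4, had a level of 2.82 ± 0.48. The core list was detected more often than other genes by Fisher's exact test, two-sided (adjusted p = 0.0179). Dppa4, named after its values were seen, was the member not detected on any array.

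Markers of the naive state, the state of mouse embryonic stem cells kept in LIF, were detected unevenly. Zfp42, which encodes Rex1, and Esrrb, an orphan nuclear receptor gene, were well above background on 0 of 3 arrays. Without a sample known to express a gene, absence of its RNA cannot be told from a probe that fails. This holds for every gene reported here on 0 arrays. Klf2 was detected at 6.09 ± 0.16 and Klf4 at −0.46 ± 0.42, both genes of Krüppel-like transcription factors. The naive list was detected in 11 of 16 cases, which did not differ from other genes (exact test, adjusted p = 0.687). Dppa3 and Pecam1 were detected in no clone and Nr0b1 in clone 1 alone, and these 3 genes are named after their values were seen. Markers of the primed epiblast, the later state from which the germ layers arise, were detected in 13 of 13 cases (exact test, adjusted p = 0.00991). Fgf5, a growth factor gene of the postimplantation epiblast, had a level of 4.05 ± 0.21. Pou3f1, which encodes Oct6, had a level of 5.54 ± 0.53. The DNA methyltransferase gene Dnmt3b had a level of 5.55 ± 0.70, and the homeobox gene Otx2 one of 0.31 ± 0.54. Whether the naive and primed lists differed from each other was not tested.

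Genes of the primitive streak and mesendoderm, where gastrulation begins, were detected in 11 of 12 cases (exact test, adjusted p = 0.0562). T, which encodes Brachyury, had a level of 3.15 ± 1.23 and Eomes one of 2.72 ± 0.37. The homeobox gene Gsc had a level of 0.99 ± 0.88, and Mixl1, another homeobox gene of the streak, one of −2.57 ± 0.96. With clone 1 left out the streak list passed the threshold (adjusted p = 0.0117 by the same exact test). Neurectoderm markers were detected in 10 of 13 cases (exact test, adjusted p = 0.456), with Sox1 at −2.73 ± 0.14 and Nes, which encodes the filament protein nestin, at 3.35 ± 0.28. Mesoderm markers were detected in 6 of 13 cases (exact test, adjusted p = 0.349), with the receptor gene Kdr at −4.10 ± 0.40 and Hand2 on 0 arrays. Primitive endoderm markers were detected in 10 of 15 cases (exact test, adjusted p = 0.795), with Gata6 at −0.97 ± 0.77 and Sox7 on 0 arrays. Trophoblast markers were detected in 6 of 12 cases (exact test, adjusted p = 0.456). Of these, Elf5, Hand1 and Gata3 were on 0 arrays and Cdx2 had a level of −0.33 ± 1.39. Germ cell markers were detected less often than other genes, in 3 of 12 cases (exact test, adjusted p = 0.0271). The germ cell genes Ddx4 and Dazl were on 0 arrays, and without clone 1 the list no longer passed (exact test, adjusted p = 0.0932).

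Markers of fibroblasts, the usual feeder cells of such cultures, were detected in 15 of 15 cases (exact test, adjusted p = 0.00991), although 1 of them, Vim, is also held by the adhesion list. The collagen genes Col1a1 and Col1a2 had levels of 1.34 ± 0.50 and 2.45 ± 0.51. Whether feeder cells were used is not given in the sources used here. Genes of adhesion and of the epithelial-mesenchymal state were detected in 16 of 17 cases (exact test, adjusted p = 0.0120). Epcam, an epithelial adhesion gene, had a level of 2.55 ± 0.58 and Cdh2, which encodes N-cadherin, one of −0.48 ± 0.33.

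Among targets of signalling pathways, those of activin and Nodal were detected in 11 of 11 cases (exact test, adjusted p = 0.0189). Nodal itself had a level of 3.84 ± 0.12 and Lefty1, its secreted antagonist, one of 5.32 ± 0.08. Targets of FGF and ERK were detected in 12 of 13 cases (exact test, adjusted p = 0.0362). Dusp6, a phosphatase gene that ERK signalling induces, had a level of 6.05 ± 0.21, and the feedback inhibitor gene Spry4 was on 0 arrays. Without clone 1 and without clone 2 the FGF list gave adjusted p values of 0.0609 and 0.0580 in the same exact test. Targets of LIF and STAT3 were detected in 12 of 12 cases (exact test, adjusted p = 0.0120), with the feedback gene Socs3 at 2.03 ± 0.14. Targets of BMP were detected in 9 of 10 cases (exact test, adjusted p = 0.139), with Id1 at −0.97 ± 0.42 and Id3 at 1.68 ± 0.27. Without clone 2 the BMP list passed (exact test, adjusted p = 0.0307). Targets of Wnt were detected in 9 of 13 cases (exact test, adjusted p = 0.795). Axin2, a general Wnt feedback gene, was on 0 arrays, while Lef1 had a level of 2.42 ± 0.14 and Sp5 one of 1.80 ± 0.76. Receptors of these factors, with the GSK3 genes, were detected in 15 of 15 cases (exact test, adjusted p = 0.00991). Fgfr1 had a level of 1.48 ± 0.13, the activin receptor gene Acvr1b one of 0.51 ± 0.17 and the LIF receptor gene Lifr one of −3.28 ± 0.37.

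Genes of the 2-cell-stage-like state were detected less often than other genes, in 0 of 7 cases (exact test, adjusted p = 0.00991). Zscan4c, the best-known marker of that state, was on 0 arrays. Y-linked genes were detected on all arrays in 0 of 4 cases (exact test, adjusted p = 0.0362), and without clone 3 the adjusted p was 0.213. Genes of X inactivation were detected in 2 of 4 cases (exact test, adjusted p = 0.687). Xist, the RNA that coats the inactive X chromosome, and its antisense gene Tsix were on 0 arrays. Imprinted genes were detected in 22 of 24 cases (exact test, adjusted p = 0.00991), with the noncoding RNA gene Meg3 at 5.26 ± 0.55 and H19 at −0.44 ± 0.88. Zim1, detected on 0 arrays, and Kcnq1ot1, detected in clone 2 alone, were the exceptions, and Zim1 is named after its values were seen. Genes of DNA methylation and Polycomb were detected in 13 of 13 cases, cell cycle genes in 14 of 14 and genes of glycolysis and hypoxia in 13 of 13 (exact test, adjusted p = 0.00991 for each). The maintenance methyltransferase gene Dnmt1 had a level of 3.61 ± 0.05, and the proliferation marker Mki67 one of 4.29 ± 0.12. Targets of p53 and genes of cholesterol synthesis were each detected in 12 of 12 cases (exact test, adjusted p = 0.0120 for each). Stress genes were detected in 10 of 11 cases (exact test, adjusted p = 0.0881) and interferon genes in 8 of 10 (exact test, adjusted p = 0.423), the latter passing without clone 1 (exact test, adjusted p = 0.0307). Reference genes were detected in 9 of 9 cases (exact test, adjusted p = 0.0285). The reference list gave adjusted p values of 0.0505 without clone 1 and 0.0507 without clone 2 in the exact test.

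In all, 29 lists were tested and adjusted together by the Benjamini-Hochberg method, and 15 were detected more often and 3 less often than other genes at an adjusted p below 0.05. Without adjustment 19 lists were below 0.05. Genes are not independent replicates, and the tests say how often members passed the background flag, not how strongly they were expressed. With the looser flag of the scanner software, which calls a spot positive and significant and was met by 15548 genes on all 3 arrays, 0 of the 29 lists passed. The lowest adjusted p was then 0.0686, and 18 lists were below 0.05 without adjustment.

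**Figure D1:**
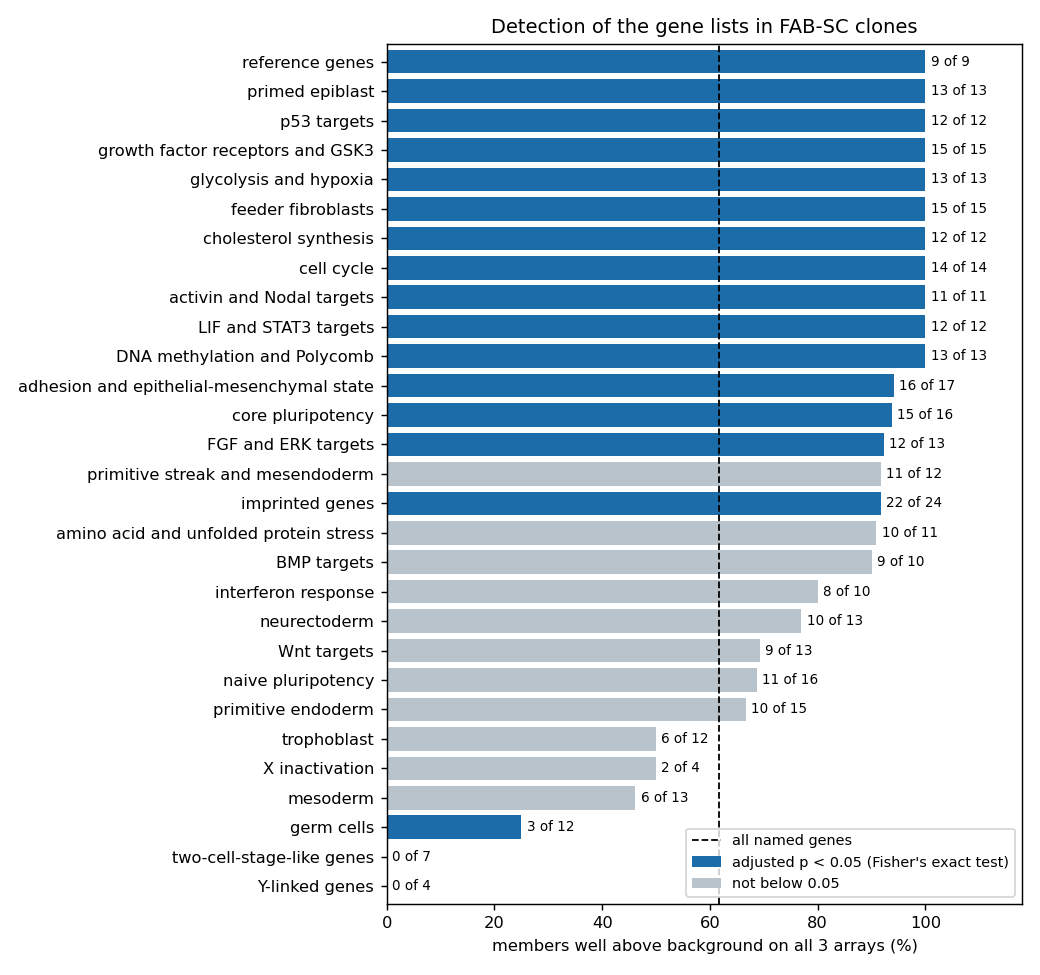
Percentage of measured members of each gene list that were well above background on all 3 arrays, with the counts beside the bars and the share of all named genes, 61.7%, as a dashed line. Blue bars mark the 18 lists with an adjusted p below 0.05 by Fisher's exact test, of which germ cells, 2-cell-stage-like and Y-linked genes lie to the left of the line.

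The next comparison asked how alike the 3 clones were. The pluripotency genes Pou5f1 and Nanog differed by at most 1.13-fold and 1.28-fold between clones, while Sox2 and Utf1 differed by 1.90-fold and 3.60-fold. The reference genes Actb and Ppia differed by 1.05-fold and 1.07-fold, and the proliferation genes Mki67, Plk1 and Top2a by 1.17-fold, 1.13-fold and 1.32-fold. The sterol synthesis gene Sqle differed by 1.14-fold. Across the 13140 genes whose probe was well above background on all 3 arrays, Pearson's r was 0.983 for clones 1 and 2, 0.991 for clones 1 and 3 and 0.984 for clones 2 and 3. Spearman's rho across the same genes was 0.983, 0.992 and 0.985, and genes are not independent replicates. The median SD of a gene over the 3 clones was 0.176 on the log2 scale. Without clone 2 the median SD was 0.104.

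The third comparison asked which genes differed between clones. Of the 20 genes with the largest ranges, 7 were highest in clone 1, among them genes known from epithelial junctions. The tight-junction gene Cldn7 was 13.8-fold higher in clone 1 than in clone 2, and its relative Cldn6 was 7.45-fold higher. Cdh1, which encodes the epithelial adhesion protein E-cadherin, was 6.39-fold higher in clone 1 than in clone 3. Kdf1, a gene of keratinocyte differentiation, was 9.75-fold higher in clone 1 than in clone 2. Mal2, a gene of apical membrane transport in epithelia, was 8.96-fold higher, and the glycosyltransferase gene Galnt3 was 9.21-fold higher, in the same pair of clones. The kinase gene Tnk1 was 17.3-fold higher in clone 1 than in clone 2, and Bspry was 7.89-fold higher in clone 1 than in clone 3.

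Other genes were highest in clone 2, in which fibroblast markers were also higher, by a median of 0.66 on the log2 scale. Prxl2a, an antioxidant gene of the peroxiredoxin-like family, was 46.5-fold higher in clone 2 than in clone 1. Ptgs1, which encodes cyclooxygenase 1, was 17.1-fold higher and Arg1, which encodes the urea cycle enzyme arginase, 13.5-fold higher in the same pair. Evx1, a homeobox gene of the posterior primitive streak, was higher in clone 2 than in clone 1 by 3.70 on the log2 scale. The cell adhesion gene Dscam was 8.93-fold higher, and the transporter gene Slc43a3 8.03-fold higher, in the same pair. Probes named for the defensin-related genes Defcr-rs2, Defcr-rs10 and Defa31 were 12.9-fold, 10.9-fold and 7.77-fold higher in clone 2 than in clone 1. These genes form a family of close copies, so which member gave the signal is uncertain. Fam171a1 was lower in clone 2 than in clone 3, with a 15.2-fold range. In clone 3 the ubiquitin ligase gene Trim25 was 12.5-fold higher than in clone 1. The hexokinase-domain gene Hkdc1 and the iron oxidase gene Heph were 9.22-fold and 7.60-fold higher in clone 3 than in clone 2.

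Within the lists, single genes differed by 2-fold or more. Utf1, a chromatin-bound pluripotency factor, was 3.60-fold higher in clone 1 than in clone 2, and 3 of 15 detected core genes differed by at least 2-fold. Cdx2, the master regulator of trophoblast and of posterior identity, was 6.69-fold higher in clone 2 than in clone 1. The early response gene Fos was 4.56-fold higher in clone 2 than in clone 1. Fst, which encodes the activin-binding protein follistatin, was 3.67-fold higher in clone 2 than in clone 1, and was the 1 gene of 11 detected activin and Nodal targets that differed by at least 2-fold. Fgfr2 was 2.23-fold higher in clone 3 than in clone 2, and was the 1 gene of 15 in the receptor and GSK3 list that did so. Of 22 detected imprinted genes, 12 differed by at least 2-fold. The imprinted gene Nnat was 4.76-fold higher in clone 3 than in clone 2, and Dlk1, a Notch ligand relative, was 3.03-fold higher in clone 2 than in clone 3. Meg3, the noncoding RNA of the same imprinted cluster as Dlk1, was 2.06-fold higher in clone 2 than in clone 3. H19 was 2.98-fold higher and Igf2 2.30-fold higher in clone 3 than in the clone with the lowest level, clone 1 for H19 and clone 2 for Igf2. Gata6 and Pim1 differed by 2.59-fold and 2.86-fold, but a second probe differed by −0.06 and 0.23 on the log2 scale in the same pairs of clones.

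By a rule of size, 1158 of 13140 genes (8.81%) differed by at least 2-fold between their highest and lowest clone, and 107 (0.814%) by at least 4-fold. Clone 2 was the clone farthest from the other two in 647 of the 1158 genes, clone 1 in 304 and clone 3 in 207. Of the 647 genes farthest in clone 2, 367 were higher there and 280 lower. With the array median as the scale, the split was 291 higher and 342 lower, and with no background filter, over all genes, it was 1218 higher and 497 lower. A second probe showed the same direction in 229 of 244 genes (93.9%) and a difference of at least 2-fold in 147 (60.2%). The count of differing genes was 657 without clone 1, 368 without clone 2 and 761 without clone 3. It was 315 with another background correction, the normexp model, 3371 among all 21301 genes with no background filter, and 702 without the genes of chromosomes 1, 2, 8, 11, 12 and 13, an alternative added after the data were seen.

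**Figure D2:**
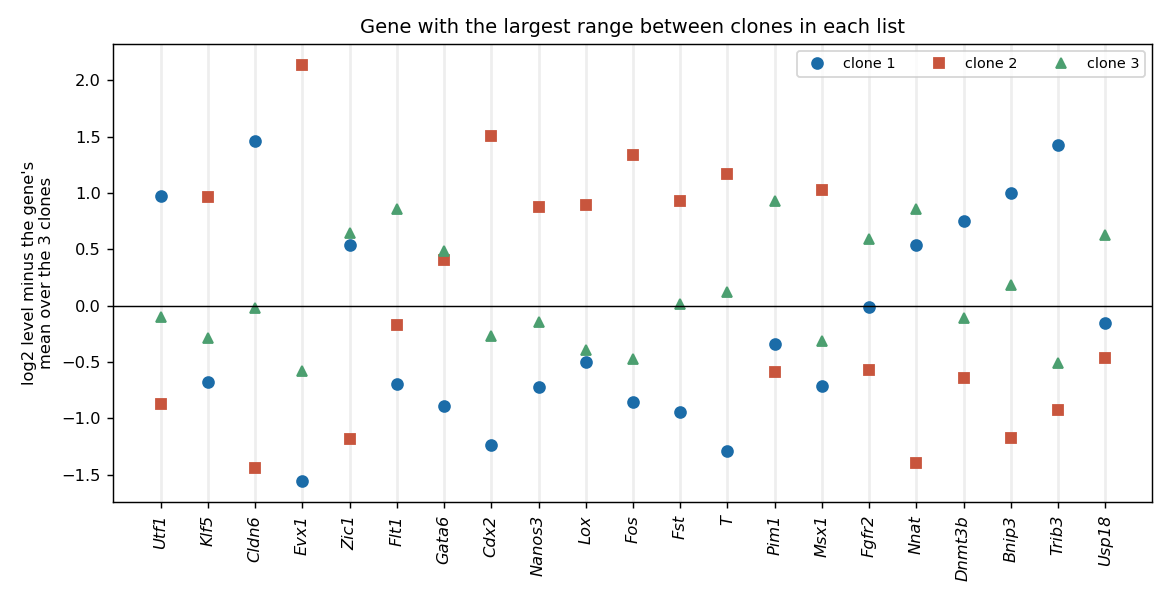
Log2 level of each clone minus the gene's mean over the 3 clones, for the gene with the largest range of at least 1 in each gene list, with 1 point per clone. Evx1 shows the widest spread, with clone 2 above and clone 1 below the mean, and Cldn6 and Trib3 have clone 1 on top.

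The fourth comparison asked which genes were detected in some clones only. Car4, which encodes a membrane-bound carbonic anhydrase, was at least 160-fold higher in clones 1 and 3 than in clone 2. Eif2s3y, a translation factor gene on the Y chromosome, was at least 70.4-fold higher in clones 1 and 2 than in clone 3. Vamp7, a gene of vesicle fusion, was at least 48.0-fold higher in clones 1 and 2 than in clone 3. Rtl6, a gene derived from a retrotransposon, was at least 46.8-fold higher in clones 1 and 3 than in clone 2, and Vtn, which encodes the adhesive glycoprotein vitronectin, was at least 14.3-fold higher in the same clones. Clone 2 alone expressed Zfp819, a zinc finger gene, at least 33.0-fold above the others, and the microtubule-associated gene Map10 at least 30.6-fold above them. Kcnq1ot1, an imprinted antisense RNA matched by its transcript identifier, was at least 23.1-fold higher in clone 2 than in the other clones. Dmc1, a recombinase gene of meiosis, was at least 14.7-fold higher in clone 2. The protease gene Ctsc was at least 20.8-fold higher in clones 2 and 3 than in clone 1. Fibroblast markers, as a list, were higher in clone 2 by a median of 0.66 on the log2 scale.

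In all, 1282 genes were detected in some clones only, 751 in 1 clone and 531 in 2 clones. A bound on the fold could be set for 1266 of them. It was at least 2-fold in 300 genes and at least 4-fold in 38, so most of these genes lay close to the background. Of the 38 genes, 10 were detected in clone 1 alone, 11 in clone 2 alone, 11 in clones 1 and 3, 3 in clones 1 and 2 and 3 in clones 2 and 3. The Y-linked genes Ddx3y, Kdm5d and Uty were on 0 arrays. Without clone 2 the count of genes detected in some clones only was 676, and with the looser background flag it was 2420.

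The fifth comparison asked whether the genes of a list moved together in a clone. Genes of the primitive streak and mesendoderm were lower in clone 1 than in the others by a median of −0.87 on the log2 scale, with 0 of 11 detected members higher there. T was 5.49-fold higher in clone 2 than in clone 1, and Gsc 3.15-fold higher in clone 3 than in clone 1. Mixl1 was 3.39-fold higher in clone 2 than in clone 1, and 7 of the 11 genes differed by at least 2-fold. Between single pairs of clones the median was −0.69 for clone 1 minus clone 2 and −1.26 for clone 1 minus clone 3. Here and below, the pair medians of lists come from runs without the remaining clone. Probes and detected members were chosen anew in these runs, so the members can differ from those behind the shifts. The shifts of 0.53 in clone 2 and 0.64 in clone 3 rested on clone 1, since without it the median for clone 2 minus clone 3 was 0.15 and that for clone 3 minus clone 2 was −0.15. Targets of Wnt, 1 of which is T, had a median of −0.89 in clone 1, with 6 of 9 lower there. Sp5 was 2.57-fold higher in clone 2 than in clone 1. For the Wnt list the pairs, with members chosen anew, gave −0.43 for clone 1 minus clone 2 and −0.39 for clone 1 minus clone 3. With no background filter the median in clone 1 was −0.06.

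Markers of fibroblasts were higher in clone 2 by a median of 0.66, or 1.58-fold, with 13 of 15 higher there. Col1a1 was 1.89-fold and Col1a2 1.94-fold higher in clone 2 than in clone 3. Lox, which encodes the collagen cross-linking enzyme lysyl oxidase, was 2.63-fold higher in clone 2 than in clone 1. Thy1, a surface marker of fibroblasts, was higher in clone 1 than in either other clone, with a range of 1.79-fold. The pairs gave 0.79 for clone 2 minus clone 1 and 0.65 for clone 2 minus clone 3. Clones 1 and 3 were alike in these markers, at −0.03 for clone 1 minus clone 3, so that their shifts of −0.35 and −0.31 rested on clone 2.

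Markers of the naive state were higher in clone 2 by a median of 0.56, with 10 of 11 detected members higher there, beside the shift of 0.66 in fibroblast markers. Klf5 was 3.13-fold and Klf4 1.67-fold higher in clone 2, each against its lowest clone. With no background filter the median shift of the naive list in clone 2 was 0.29, a percentile of 97.2, just inside the range of random lists. The shift of −0.38 in clone 3 was lost without clone 2, at −0.02. Markers of the primed epiblast were lower in clone 2 by a median of −0.53, with 9 of 13 lower there, again beside the shift in fibroblast markers. Dnmt3b was 2.63-fold higher in clone 1 than in clone 2, and Pou3f1 had levels of 5.93 and 4.93 in these clones. The pairs gave −0.44 for clone 2 minus clone 1 and −0.34 for clone 2 minus clone 3. In clone 1 the primed list stood at 0.22, and at 0.44 without clone 3.

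Genes of glycolysis and hypoxia were lower in clone 2 by a median of −0.41 and higher in clone 1 by 0.39, each in 11 of 13 members, beside the shift of 0.66 in fibroblast markers. Bnip3, a mitophagy gene induced in hypoxia, was 4.52-fold higher in clone 1 than in clone 2. The kinase gene Pdk1, which restrains the use of pyruvate by mitochondria, was 2.69-fold higher, and the glycolytic gene Pgk1 was 1.68-fold higher, in the same pair. The glycolysis pairs gave 0.51 for clone 1 minus clone 2 and 0.24 for clone 1 minus clone 3, and −0.28 for clone 2 minus clone 3. Targets of p53 were lower in clone 2 by a median of −0.32, with 9 of 12 lower there. The apoptosis gene Bbc3 was 1.87-fold higher in clone 1 than in clone 2. The p53 shift of 0.27 in clone 3 was lost without clone 2, at 0.06, and that of clone 2 was −0.16 without the genes of chromosomes 1, 2, 8, 11, 12 and 13, where it fell inside the range of random lists. Interferon genes were higher in clone 3 by a median of 0.47, with 7 of 8 higher there. Isg15 was 1.88-fold higher in clone 3 than in clone 1, and Usp18, which removes Isg15 from proteins, 2.13-fold higher in clone 3 than in clone 2. Stress genes were higher in clone 1 by 0.29, where Trib3, a pseudokinase gene of the stress response, was 5.10-fold higher than in clone 2. The stress list had a median of −0.35 in clone 3, and of 0.03 for clone 3 minus clone 2, without clone 1.

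Medians in clone 1 were also below those of random lists for mesoderm, with −0.44, and for BMP targets, with −0.37. The BMP median lay inside their range without clone 3, at −0.28. Msx1, a homeobox target of BMP, was 3.33-fold higher in clone 2 than in clone 1. Flt1, a VEGF receptor gene, was 2.93-fold higher in clone 3 than in clone 1. The core pluripotency, primitive endoderm, FGF, LIF and imprinted lists each had a median outside the range in at least 1 clone. The largest of these, 0.36 for primitive endoderm in clone 3, was 0.16 without clone 1 and then inside the range. The lists of neurectoderm, trophoblast, adhesion, activin and Nodal targets, receptors and GSK3, DNA methylation and Polycomb, cell cycle, cholesterol synthesis and reference genes stayed inside the range of random lists in all 3 clones. For the cell cycle list the medians were 0.00, 0.02 and −0.04 in clones 1, 2 and 3. In the adhesion list the median and the mean differed in sign in clone 1, at −0.06 and 0.31.

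Over 25 lists and 3 clones, 31 of 75 medians lay outside the central 95% of random lists matched on level, where chance gives 3.75. The spread between clones was above the range of random lists in 13 of 25 lists and below it in 0, where chance gives 1.25 in all. These chance counts hold for separate lists of unrelated genes. The lists share members, their genes are not independent, and a gene's 3 shifts sum to 0, so the 75 values are not separate. Without clone 1, 14 of the remaining 50 medians lay outside. In a pair of clones the medians of a list are the same difference with opposite signs, so a list counts under each clone or under none. The lists with a spread that high numbered 8 without clone 1 and 7 without clone 3. These ranks describe 3 arrays and carry no p-value.

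**Figure D3:**
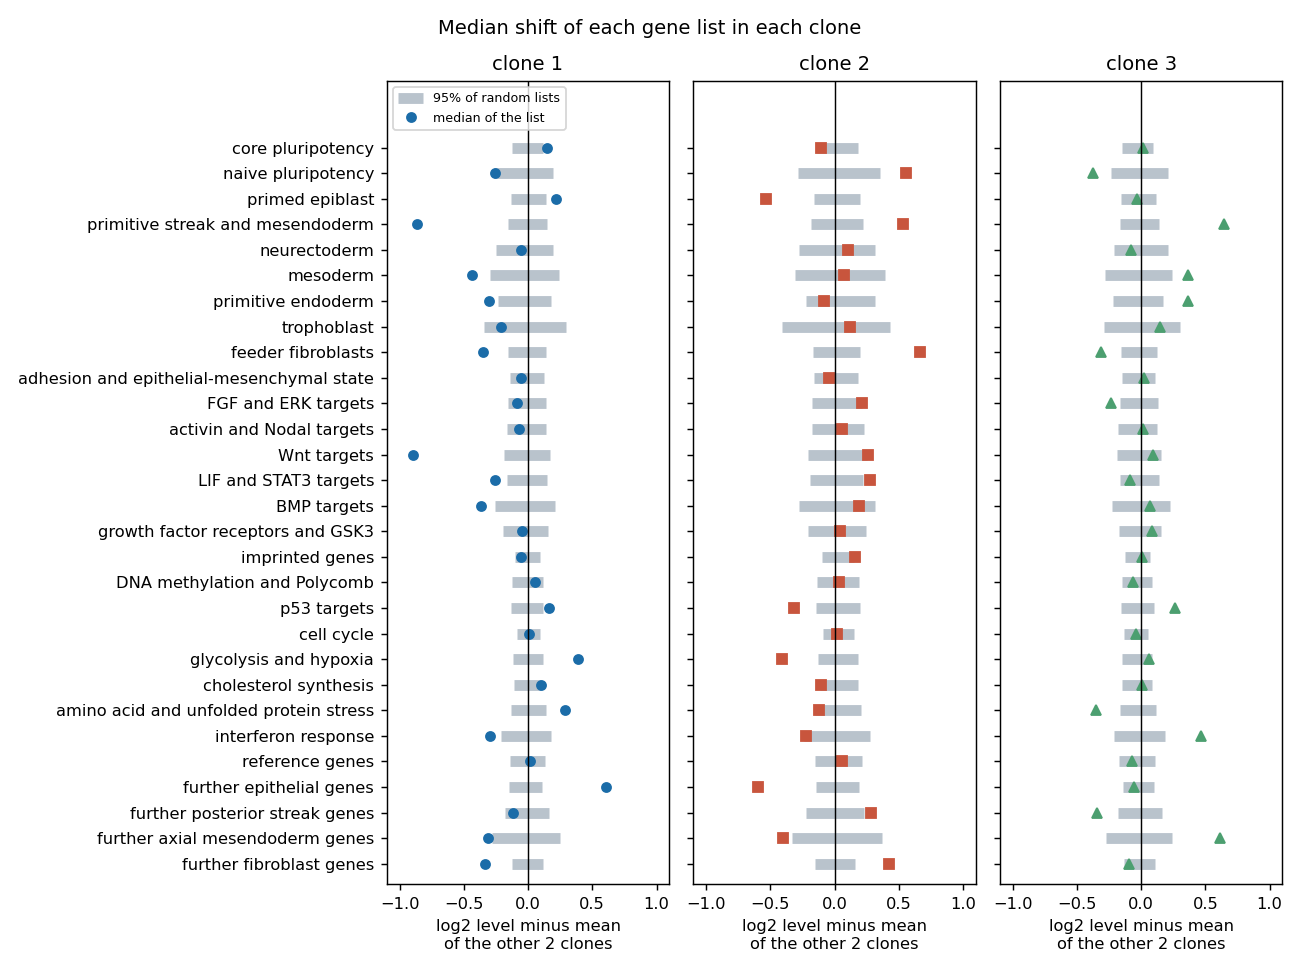
Median over detected members of each clone's log2 level minus the mean of the other 2 clones, for each gene list (coloured points), with the central 95% of 10000 random lists matched on level (grey bars). Primitive streak genes lie at −0.87 in clone 1 and fibroblast markers at 0.66 in clone 2, and the lists named further were added after the data were seen.

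The last comparison asked whether the genes of a chromosome moved together, as they would in a clone that gained or lost it. Genes of chromosome 8 were higher in clone 2 than in the others by a median of 0.44, or 1.35-fold, in 600 of 684 genes (87.7%). Genes of chromosome 12 were higher in clone 2 by a median of 0.44, or 1.36-fold, in 370 of 439 genes (84.3%). Fibroblast markers were higher in clone 2 as well, by 0.66. On chromosome 8 the median was 0.53 for clone 2 minus clone 3, 0.36 for clone 2 minus clone 1 and −0.16 for clone 3 minus clone 1. On chromosome 12 it was 0.43 for clone 2 minus clone 3 and 0.46 for clone 2 minus clone 1, while clones 1 and 3 did not differ, at 0.00. Split into 4 parts of equal gene number in gene order, chromosome 8 stood in clone 2 at 0.40, 0.38, 0.53 and 0.45. The parts of chromosome 12 stood at 0.10, 0.58, 0.50 and 0.51. The last part of chromosome 2 was lower in clone 2, at −0.55, and the last part of chromosome 1 was higher there, at 0.28. In clone 1 the last 2 parts of chromosome 11 were both at 0.24. The named genes Meg3, Dlk1 and Fos, higher in clone 2, lie on chromosome 12, and Nnat, Trib3 and Dnmt3b, lower in clone 2, on chromosome 2. Other named genes of chromosome 2 went the other way, as Ptgs1, Slc43a3 and Sp5 were higher in clone 2 than in clone 1. Whether the change of a single gene came with its chromosome was not tested. Cdh1 lies on chromosome 8 but was higher in clone 1.

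Over 20 chromosomes and 3 clones, 26 of 60 medians lay outside the central 95% of random lists, where chance gives 3. Neighbouring genes are not independent, and a chromosome holds so many genes that a very small shift can pass. Among the genes that differed most and were higher in clone 2, 67 of 367 (18.3%) lay on chromosomes 8 and 12, against 8.55% of the genes measured. Without clone 3, 16 of the remaining 40 medians lay outside, where each chromosome counts under each clone of the pair or under none. DNA was not measured.

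**Figure D4:**
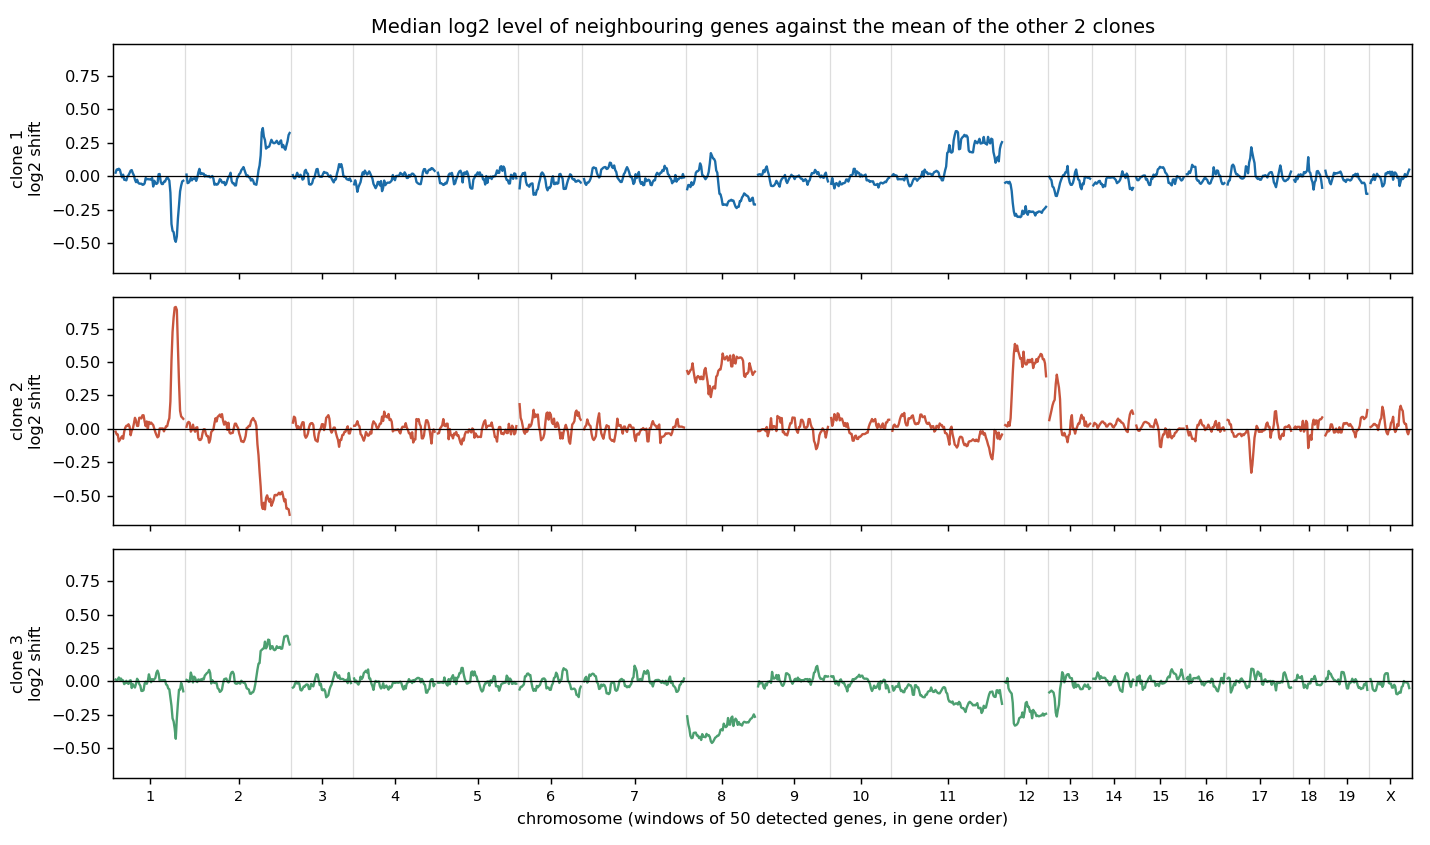
Median log2 level of 50 neighbouring detected genes minus the mean of the other 2 clones, along each chromosome in gene order, for clones 1, 2 and 3 from top to bottom. Clone 2 lies well above 0 along chromosome 8, close to 0 at the start of chromosome 12 and well above 0 along the rest of it, and below 0 at the end of chromosome 2, and clone 1 lies above 0 along the later part of chromosome 11.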

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

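A signal appeared in probes that no comparison used: of 6444 probes without a gene name, 1847 (28.7%) were well above background on all 3 arrays, and 125 of these (6.77%) differed by at least 2-fold between clones.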

How the results depend on the processing

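The runs without the genes of chromosomes 8 and 12, or of chromosomes 1, 2, 8, 11, 12 and 13, were chosen after the results had been seen. Signal over background limits what these arrays show of dim genes. With the normexp background correction, whose offset of 50 compresses dim signals by construction, the agreement between clones had a median SD of 0.123 in place of 0.176, and the genes differing between clones numbered 315 in place of 1158. With no background filter 3371 of 21301 genes differed, more genes by construction but also a larger share (15.8%, against 8.81%). With a 4-fold rule 107 differed. Without chromosomes 1, 2, 8, 11, 12 and 13, 702 of 8810 genes differed (7.97%, against 8.81% of all). With the positive-and-significant flag 2420 genes were detected in some clones only, and 0 lists passed the detection test in place of 18, where a larger share of all genes, 73.0%, met the flag. The cause of the other changes was not tested.

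Leaving out 1 clone gave a median SD for the agreement between clones of 0.104 to 0.162, and 368 to 761 genes differing between clones. The lists with a high spread numbered 7 to 13, list shifts outside the range 14 to 24 of 50, and chromosome shifts 16 to 18 of 40, with fewer values by construction. These shifts mirror each other within a pair, so each list or chromosome counts under each clone of the pair or under none. Genes detected in some clones only numbered 676 to 983, and 17 lists passed the detection test in each run. A shift turned its direction with 1 clone left out in 8 cases. It is then the difference of a single pair, with probes and detected members chosen anew. The range was −0.15 to 1.26 for primitive streak and mesendoderm in clone 3, −0.040 to 0.46 for mesoderm in clone 3, −0.65 to 0.027 for feeder fibroblasts in clone 3 and −0.39 to 0.026 for amino acid and unfolded protein stress in clone 3. It was −0.49 to 0.043 for interferon response in clone 1, −0.55 to 0.10 for further posterior streak genes in clone 3, −0.56 to 0.11 for further axial mesendoderm genes in clone 1 and −0.43 to 0.0044 for chromosome 12 in clone 3.

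Under the 8 settings other than leaving out a clone, 335 values of 44 shifts of lists and chromosomes kept their direction, with 0 turned. Of these values 88 moved by at least the SD of the medians of random lists. Some fell inside the range of random lists, such as Wnt targets in clone 1 with no background filter, at −0.06. The ranges of 41 named genes kept their direction in 246 of 246 values, and 10 moved by at least the gene's SD over clones, under the normexp correction. The count of genes differing between clones was 1027 to 1152 under the settings not given above. The list shifts outside the range numbered 24 to 33, and those of chromosomes 26 to 28. With the array median as the scale the median shift of all genes was 0.06 in clone 1 and −0.05 in clone 2, against −0.01 and 0.02. The deposited table gave a median SD of 0.170 over its 19765 entries above the median in all clones. It could not be run for single genes, lists or chromosomes, since its entries have no names.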

Other observations

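The lists of further epithelial, posterior streak, axial mesendoderm and fibroblast genes, the places along chromosomes the test of the first part of chromosome 12, the test of epithelial genes without 6 chromosomes and the limit of the scaling tests to normexp and quantile normalization were chosen after the results had been seen. Genes of axial mesendoderm, the tissue that forms the notochord, were higher in clone 3 by a median of 0.61 on the log2 scale. Of the detected members, 7 of 7 were higher there. Foxj1, a gene of motile cilia, was 4.54-fold higher in clone 3 than in clone 2, and Frzb, which encodes a secreted Wnt antagonist, 3.62-fold higher in the same pair. Both genes are named after their values were seen. The shifts of −0.31 in clone 1 and −0.40 in clone 2 were lost without clone 3, at 0.11 and −0.11. Genes of the posterior streak were higher in clone 2 by a median of 0.28, with 10 of 13 higher there, beside a shift of 0.66 in fibroblast markers. Hoxb1, named after its values were seen, was 4.51-fold higher in clone 2 than in clone 1. The pairs gave 0.55 for clone 2 minus clone 3 and 0.51 for clone 2 minus clone 1. With the normexp correction the shift in clone 2 was 0.15, and without the genes of chromosomes 8 and 12 it was 0.18, both inside the range of random lists. The shift of −0.34 in clone 3 turned to 0.10 without clone 2. Further epithelial genes stood at 0.60 in clone 1, with 21 of 25 higher there, and at −0.59 in clone 2, with 20 of 25 lower there, beside the shift in fibroblast markers. Their pairs gave 0.87 for clone 1 minus clone 2, 0.53 for clone 1 minus clone 3 and −0.30 for clone 2 minus clone 3. Both fibroblast lists together stood at −0.35 in clone 1, with 33 of 36 lower there, and at −0.10 for clone 1 minus clone 3, without clone 2.

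Stretches of chromosomes stood apart as well, as medians of 50 neighbouring genes or on the sides of a single fitted step. The place of a step is given as the central 95% of 200 redraws of the genes. Each stretch of 50 genes named is the one farthest from 0 on its chromosome in that clone, so its size is a selected extreme. No range of random stretches was drawn. Steps were fitted only where the parts of a chromosome differed by at least 0.2 in a clone. On chromosome 1 the genes from Usp21 to Parp1 were higher in clone 2 by 0.91, or 1.88-fold. On chromosome 2 the step in clone 2 lay between Tmx4 and Nxt1, from 0.01 over 706 genes to −0.55 over 309 genes, 12.3% of which were higher there. On chromosome 11 the step in clone 1 lay between Ssh2 and Rab34, from 0.00 over 530 genes to 0.25 over 540 genes. On chromosome 8 a step in clone 1 lay between Hmox1 and Abce1, where clone 1 minus clone 2 went from −0.24 to −0.45 and clone 1 minus clone 3 from 0.26 to 0.08. Clone 2 minus clone 3 was 0.51 before that step and 0.54 after it. On chromosome 13 the genes from H2bc4 to Fars2 were higher in clone 2 by 0.41, or 1.32-fold. On chromosome 17 the genes from Brpf3 to Zfp763 stood at −0.33 in clone 2. Of the Y-linked genes, Eif2s3y had levels of 0.68 and 1.33 in clones 1 and 2 and was not above background in clone 3. Rbmy was detected in clones 1 and 2, at least 2.97-fold above clone 3, and Zfy1 in all 3 clones, both named after their values were seen. Fibroblast markers were higher in clone 2 by 0.66.

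Genes of chromosomes 8 and 12 were higher in clone 2, and a candidate explanation is a gain of DNA in that clone. On chromosome 8, clone 3 was also lower than the others, by a median of −0.34, in 588 of 684 genes. Each shift is relative to the other clones, so on chromosome 8 a gain in clone 2 cannot be told from a loss in clone 3. A few strongly changed genes cannot move a median over so many genes. That at least 84.3% of the genes of each chromosome were higher in clone 2 is therefore no separate test of them. As to scaling between arrays, chromosomes 8 and 12 were at a percentile of 100 under the normexp correction and quantile normalization. With the normexp correction they stood at 0.32 and 0.29, the lowest values under other scalings and corrections. The random lists, matched on level, pass through the same scaling, so this test could hardly have come out otherwise and decides nothing on scaling. It shows only that these genes stood apart from genes of like level on the same arrays. The median of all genes in clone 2, 0.02, is set largely by the scaling itself and decides nothing here. A gain of all of chromosome 8 remains open, as its 4 parts each lay at a percentile of 100, but clone 2 exceeded clone 1 unevenly along it, by the step in clone 1. For chromosome 12 the criterion set beforehand for a gain of all of it, every part above the range of random lists, was met. Its first part, 110 genes at 0.10, was at percentile 98.4 among these lists. Equally many genes drawn from the rest gave 0.47 to 0.59, so that the first part lay at percentile 0 of the draws. This comparison was chosen after the low first part had been seen, so its percentile is no independent test. A fitted step between Sypl and Bzw2 went from 0.03 to 0.53. The sizes of these shifts argue against an equal gain along all of chromosome 12. DNA was not measured, so a gain in part of the cells and other causes stay open.

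Epithelial genes were higher in clone 1, and a candidate explanation is a wider epithelial gene programme in that clone. On further epithelial genes the median shift in clone 1 was 0.60, with 21 of 25 higher there, at a percentile of 100 among random lists, and it was 0.34 with the normexp correction. St14, an epithelial protease gene named after its values were seen, was 4.03-fold higher in clone 1 than in clone 2. As to scaling between arrays, the percentile of the list was 100 under the normexp correction and quantile normalization. The random lists, matched on level, pass through the same scaling, so this test could hardly have come out otherwise and decides nothing on scaling. It shows only that the list stood apart from genes of like level on the same arrays. The median of all genes in clone 1, −0.01, is set largely by the scaling itself and decides nothing here. Members on chromosomes 1, 2, 8, 11, 12 and 13 are argued against, since without these the shift was 0.56 at a percentile of 100. Chromosome 17, where the stretch from Brpf3 to Zfp763 stood at 0.22 in clone 1, was not left out, so its members stay open. Without chromosomes 8 and 12 alone the percentile was also 100, which decides nothing, as their genes were lower in clone 1. A difference between cultures in density or state, or between slides, or an effect of extra copies on genes elsewhere, was not tested and stays open, as each clone had 1 array.

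Fibroblast markers were higher in clone 2, and a candidate explanation is a larger share of feeder fibroblasts in that culture, although the sources used here name no feeder cells. The test on further fibroblast genes went with it, with a median shift in clone 2 of 0.42, 15 of 21 higher there, at a percentile of 100, but 0.22 with the normexp correction, 0.34 without the genes of chromosomes 8 and 12 and 0.26 for clone 2 minus clone 3. That the members on chromosomes 8 and 12 carry the shift is argued against, since without them both fibroblast lists together stood at 0.48, at a percentile of 100, but an effect of extra copies on genes elsewhere was not tested. Of the abundant fibroblast genes Col1a1 and Col1a2 were 1.89-fold and 1.94-fold higher in clone 2 than in clone 3, while Acta2, named after its values were seen, had levels of 4.36, 4.40 and 4.70 in clones 1, 2 and 3. Expression of these genes by the stem cells themselves stays open, since 1 gene of the first list, Vim, is also held by another list and the arrays cannot assign RNA to a cell type.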
